A study of Saccharomyces cerevisiae with 23 samples.

How the data were processed

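Total RNA was extracted with the Ambion Ribopure yeast kit and made into libraries with the NuGEN Ovation Universal system and random hexamers, per the labels' protocols. The 23 libraries are of 1 strain, 1 library per time from 0 to 10 h after transfer to sporulation medium. The authors deposited 1 table per library with FPKM per gene and its lower and upper confidence bounds, per the file headers. The bounds are taken here as 95% bounds, a level that the header names do not give. Per the submitters' processing notes, Bowtie and Cufflinks 2.2.1 were used with the builds R64 and sacCer3; the Bowtie version, the annotation, the strand setting and any filter are not given in the sources used here. FPKM was not checked for strand, so a gene and its antisense partner cannot be told apart, and overlaps with other rows of at least 40% are given where a gene is named. An FPKM of a very short RNA is unstable because it is divided by a small effective length.

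Each table gave 7132 rows beside a few lines that are not reported here. Rows were joined by identifier, or by position where the identifier is blank. Left out were 11 rows with too many fragments for an estimate (ribosomal DNA) and 254 rows that name no gene, which held at most 0.0161% of the implied fragments of a library; 6867 rows were used. Of the systematic identifiers, 6022 of 6716 matched the RefSeq annotation and 99.4% of those had the same position. RefSeq symbols were used where they differ from the file. The 8 genes of the mitochondrial genome list are listed at 0 in every library and were not tested.

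Depth was read from the bounds. With F the FPKM and U its upper bound, the number of fragments behind a value was taken as the square of 2F / (U - F), which assumes that the bounds are counting bounds of 2 standard errors. Mapped fragments were read from the slope of fragments per FPKM on gene length, over 152 to 661 long genes that overlap no other row and have whole implied numbers. This gave 2554679 to 4238313 mapped fragments per library, of which 14.4% to 34.6% fell on listed genes. The remainder, 2185748 to 2770910 fragments, varied little between libraries, and what the authors' mapped total counts is not given in the sources used here, so the share on listed genes is relative to the total behind the deposited FPKM, whatever that total holds. The implied numbers up to 200 were whole, within 0.05, for 40.2% to 64.7% of genes in a library, so whole reads could not be recovered and no count test was run. All bounds cover counting error only. The RNA gene SNR39B took 8.14% to 48.7% of the summed FPKM of a library.

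Values were analysed as log2(FPKM + 1), so a log2 change understates the change of low genes. The 6560 genes with a mean over all libraries of at least 1 FPKM were tested; 307 were not. The time test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) with a natural cubic spline of 4 degrees of freedom over the 22 libraries from 2 h on. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fitted range of at least 1, and as a rise or a fall by its larger departure from the fitted 2 h value. The window contrasts used limma on the same libraries in 4 groups of 5, 6, 6 and 5 consecutive libraries, called at an adjusted p under 0.05 and an absolute log2 change of at least 1. All limma tests are two-sided. The median lag-1 autocorrelation of residuals was 0.05 for the spline and 0.14 for the windows. The libraries of a window are not replicates, and nothing in the labels says that they came from separate cultures. The contrast of 2.25 to 3 h with 2 h was added after the data were seen.

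The windows, the main tests, the 22 gene lists and the rule for named genes were chosen before the data were examined. For 2 listed names no row was found. Lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance; p-values were adjusted over the 21 lists with at least 3 tested members. The only lists that passed with an estimated correlation were recombination and synapsis in the added contrast and spore wall and late genes in the contrast of 4.75 to 6 h with 3.25 to 4.5 h. Single libraries at 0 and 2 h were compared without a test, for genes of at least 10 FPKM in either. Peak times were compared by permutation with 100000 resamples (SciPy 1.17.1).

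By the rule for named genes these were IME1, IME4, NDT80 and CUP1-1, then per contrast the 10 largest rises and 8 largest falls among called genes with a standard name, separated windows and at least 10 FPKM in a window, then up to 4 called members of each list, and for 2 h against 0 h the 8 largest rises and falls. Not every gene under the rule is named in the text. DIT1, SPS100, RNR1, POL1 and CTR1, and RPL3 and NSR1 at 8 and 10 h, were chosen after their values were seen. Alternatives were other pseudocounts, filters, scaling, quantile normalisation, splines and window borders, robust moderation, leaving out each library, and, added later, genes overlapping no other row, rows of at least 300 bases, the series without the 4.5 and 7.5 h libraries, fry after scaling, and the lists of the last contrast without the 10 h library. Median-of-ratios scaling used 5046 genes.

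The tests were checked on values simulated for 6560 genes from the real means and residual spreads, with normal noise and 200 genes of a mean of at least about 5 FPKM stepped up or down from 4.75 h on. In the contrast of 4.75 to 6 h with 3.25 to 4.5 h, calls recovered 14% of genes changed by 1 on the log2 scale, 70% of those changed by 2, 92% by 3 and 94% by 4, with 7 false calls. A window call needs an estimated change of at least 1. The median estimate for genes changed by 1 was 0.98, so many missed that cut whatever their p-value. The time test recovered 16%, 56%, 84% and 94%, with 6 false calls. The simulated noise was independent between libraries and between genes and held no trend within windows. The false calls therefore do not measure those to be had in the real course.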

Results

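Budding yeast was followed through a synchronised meiosis. In the strain used, IME1, the master activator of entry into meiosis, and IME4, an RNA methyltransferase of early meiosis, stand under the copper-responsive CUP1 promoter, as the series title states. Cells were moved to sporulation medium, and copper sulphate was added at 2 h to switch both genes on. RNA-seq of total RNA gave 23 libraries: 1 at 0 h, 5 from 2 to 3 h, 6 from 3.25 to 4.5 h, 6 from 4.75 to 6 h and 5 from 6.5 to 10 h. Each time has 1 library, so there are no replicates, and the 4 runs of consecutive times from 2 h on serve as windows. A mean ± SD below is over the consecutive libraries of a window, and p-values measure the spread around a window mean or a smooth curve of what the labels present as a single course. The deposited values are FPKM, a fragment density scaled to gene length and library depth. In all, 6560 genes with a mean of at least 1 FPKM were tested. The authors' confidence bounds imply between 368931 fragments on listed genes in the 7.5 h library and 1467404 in the 4.75 h library. The median gene lay at 18.3 FPKM in the 4.75 h library and at 2.32 FPKM in the 7.5 h library, as the plot of library levels shows.

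**Figure D1:**
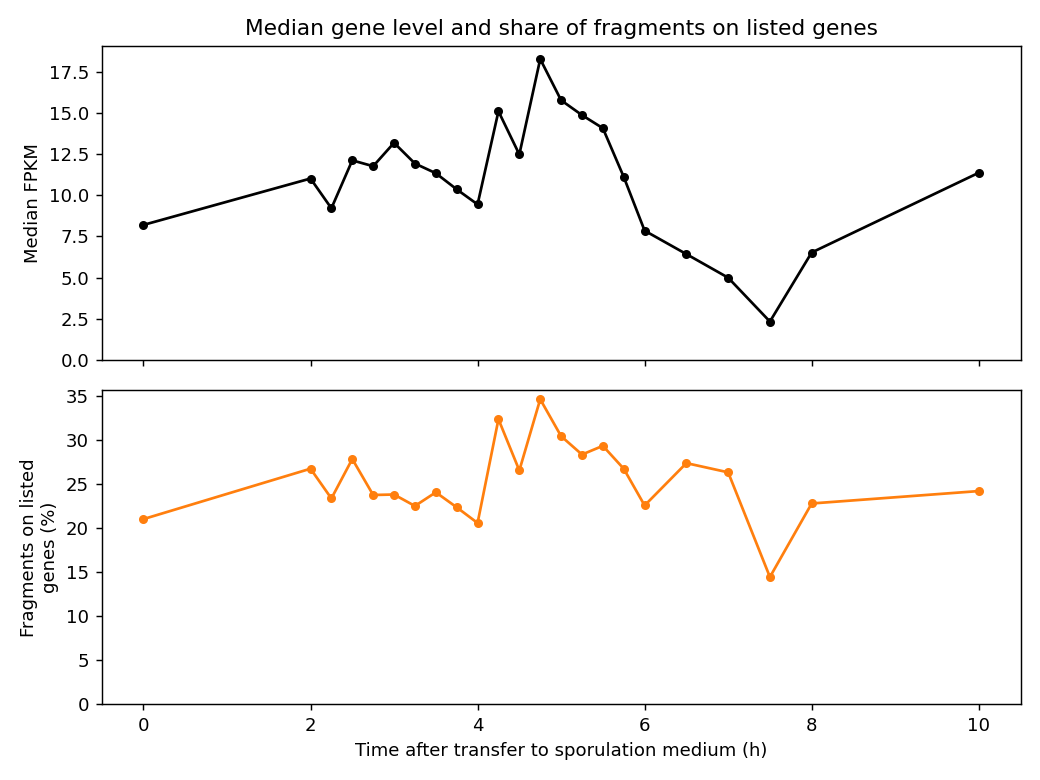
Median FPKM over genes (upper panel) and percent of implied mapped fragments that fall on listed genes (lower panel) in each of the 23 libraries, against hours after transfer to sporulation medium; each point is 1 library and both vertical axes start at 0. The median fell from 18.3 FPKM at 4.75 h to 2.32 FPKM at 7.5 h, and the share on listed genes from 34.6% to 14.4%. At 10 h they were 11.4 FPKM and 24.2%.

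The induced genes are given first, since they check the labels. IME1 (YJR094C, chromosome X, 604569 to 605651) was at 40.4 FPKM at 0 h, 818 FPKM at 2 h, 7908 FPKM at 2.25 h and 9734 FPKM at 2.5 h, its highest library. IME4 (YGL192W, chromosome VII, 142246 to 144048) was at 6.08 FPKM at 0 h, 89.7 FPKM at 2 h, 2615 FPKM at 2.25 h and 2950 FPKM at 2.5 h. Both had lower values at 3.25 h, 1624 FPKM for IME1 and 561 FPKM for IME4. They stood at 2978 and 1025 FPKM at 5.5 h and at 101 and 54.3 FPKM at 7.5 h. Over the 22 libraries from 2 h on, limma's spline test gave adjusted p = 5.61e-05 for IME1 and 0.00246 for IME4. Their fitted ranges were 5.29 and 4.19 on the log2 scale. The spline test covers the whole course, the late fall included, and is not a test of the copper induction. CUP1-1, the copper metallothionein whose promoter drives both genes, was at 49.6 FPKM at 0 h, 126 FPKM at 2 h and 5702 FPKM at 2.5 h, and missed the test (limma adjusted p = 0.0732). CUP1-1 and CUP1-2 are near-identical copies and each lies wholly under another row, so the value of either is uncertain. IME2, the kinase that IME1 activates, was at 3.44 FPKM at 2 h and 405 FPKM at 2.25 h. NDT80 (YHR124W, chromosome VIII, 356561 to 358444), the activator of the middle genes, stayed at or below 5.51 FPKM in every library up to 4 h, was at 19.4 FPKM at 4.25 h and peaked at 438 FPKM at 6.5 h.

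**Figure D2:**
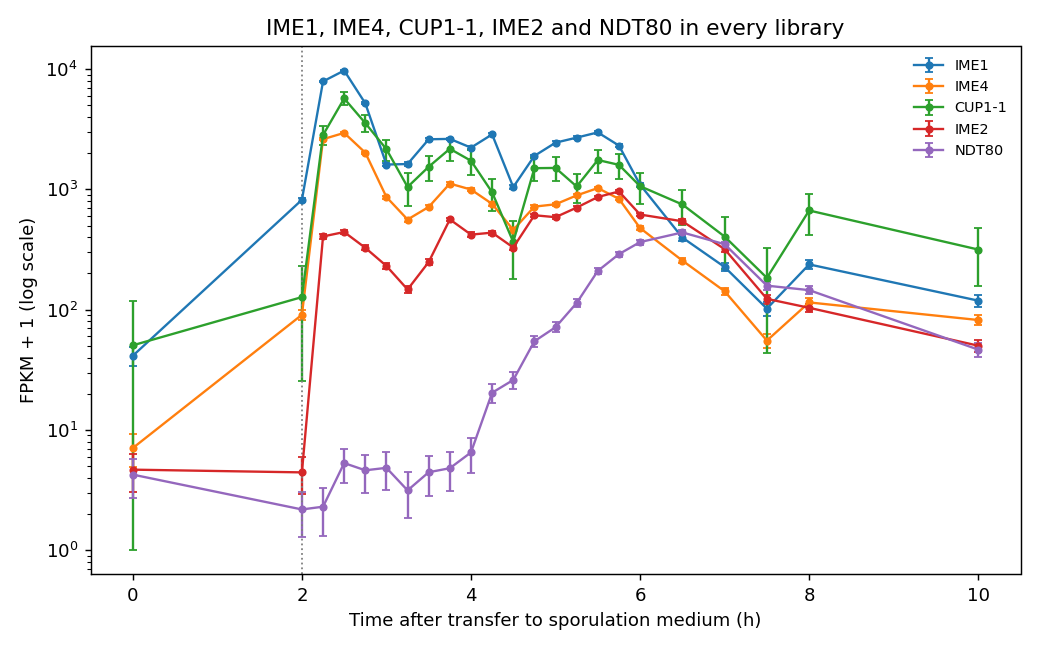
FPKM + 1 (log axis) of IME1, IME4, CUP1-1, IME2 and NDT80 in each of the 23 libraries against hours after transfer; points are single libraries, bars are the authors' 95% bounds and the dotted line marks 2 h, when copper was added. IME1 went from 818 FPKM at 2 h to 7908 FPKM at 2.25 h, and NDT80 from 5.51 FPKM at 4 h to 438 FPKM at 6.5 h.

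Which genes changed at any time between 2 and 10 h was asked with a moderated F test of a spline of time. Of 6560 genes, 5447 passed with limma's adjusted p under 0.05 and a fitted range of at least 1 on the log2 scale, 2038 as a rise from 2 h and 3409 as a fall. After median-of-ratios scaling 5114 passed, 2499 as a rise and 2615 as a fall, and 4330 genes had the same call both ways. The split between rises and falls therefore rests on the scaling. Fitted maxima below are those of a smooth curve and can lie away from the highest library. The only library after 8 h is at 10 h, so a late maximum can be the edge of a curve still rising. Among the rising genes the fitted maximum lay after 3 h and up to 4.5 h for 398, after 4.5 h and up to 6 h for 441, after 6 h and up to 8 h for 605, and after 8 h for 594. HTB2, a histone H2B gene, had its fitted maximum at 3.45 h with a range of 6.35 (limma adjusted p = 5.29e-09). NDT80 had it at 6.9 h with a range of 6.88 (limma adjusted p = 1.18e-11). DIT1, an enzyme of the dityrosine layer of the spore wall, was at 13.1 FPKM at 7.5 h, 928 FPKM at 8 h and 1471 FPKM at 10 h (limma adjusted p = 3.41e-06). SPS100, a late spore wall gene, stayed at or below 7.85 FPKM in every library up to 8 h and was at 120 FPKM at 10 h. TDH3, the main glyceraldehyde phosphate dehydrogenase, fell over a range of 5.86 (limma adjusted p = 2.03e-09), from 240 FPKM at 2 h to 5.17 FPKM at 4 h.

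The 2 h library was set against the 0 h library. Copper was added at 2 h, and the time label does not say whether this library was taken before or after the addition. An effect of the medium and an early response to copper therefore cannot be told apart in this comparison. MEP2, an ammonium permease, went from 0.937 FPKM at 0 h to 323 FPKM at 2 h, GAP1, the general amino acid permease, from 7.75 to 273 FPKM, and DAL80, a regulator of nitrogen use with 50.2% of it overlapping another row, from 2.80 to 107 FPKM. LEU1, of leucine synthesis, went from 5.83 to 468 FPKM, MET17, of sulphur amino acid synthesis, from 2.15 to 77.8 FPKM, and NCE103, a carbonic anhydrase, reached 1548 FPKM (log2 ratio 6.01). DAL5, an allantoate permease, went from 0.425 to 45.7 FPKM and DAL3 from 0.789 to 43.5 FPKM. The nitrogen starvation and autophagy list had a median log2 ratio of 1.38, above 100% of 10000 random lists matched on level, and 17 of its 29 members were at least 2-fold higher. Genes of a list tend to move together and those of a random list do not, so such ranks are easily extreme. Lower at 2 h were ARO10, a decarboxylase of amino acid breakdown (231 to 13.5 FPKM), the hexose transporters HXT7 (90.1 to 4.89 FPKM) and HXT6 (76.0 to 4.33 FPKM), which are near-identical copies. So were TDH1 (326 to 24.6 FPKM), GNP1 (55.5 to 3.69 FPKM) and ASC1 (32.9 to 0.751 FPKM). ADF1, which lies wholly under another row, and RPL34B, listed at 0 at 2 h, were lower too, but their 95% bounds at 0 h reach down to 1.64 and 2.05 FPKM.

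Ribosome biogenesis genes had a median log2 ratio of -1.31 between 0 and 2 h, below all 10000 random lists, and 50 of 80 were at least 2-fold lower. Copper and iron uptake genes had a median of -1.24 with 12 of 22 at least 2-fold lower, among them CTR1, the main copper transporter, at 97.1 FPKM at 0 h and 23.7 FPKM at 2 h. The 4 copper-activated genes had the highest median of any list, 1.75 (1.34 after scaling), with 3 at least 2-fold higher, and IME1 and IME4 stood higher at 2 h as well. The authors' bounds at 0 and 2 h are apart for IME1 (47.9 FPKM at most at 0 h, 786 FPKM at least at 2 h) and IME4 (8.23 and 81.6 FPKM), but overlap for CUP1-1. Of 3965 genes at 10 FPKM or more in either library, 1367 differed at least 2-fold, 994 higher and 373 lower at 2 h. After scaling 1218 did, 573 higher and 645 lower, and the median of these genes moved from 0.39 to -0.01. These are single libraries with no replicate check, and the bounds cover counting error only. By the planned rule, the largest ratios belonged, apart from ASC1, to small RNA genes listed at 0 in 1 of the libraries. These were SNR79, SNR55, SNR50, SNR66, SNR73, SNR68, SNR24 and SNR78 at 0 h, and IMT3, SNR57, SNR74, SNR72, SNR62, SNR48 and SNR44 at 2 h; SNR24 and SNR44 lie wholly within ASC1 and RPS22B, and 76.4% of SNR73 overlaps another row. The genes named above are therefore those of at least 300 bases, a limit chosen after their values were seen.

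Genes of recombination stood higher in each library from 2.25 to 3 h than at 2 h, with list medians of 2.13 FPKM at 0 h, 2.36 FPKM at 2 h and 55.0 FPKM at 2.25 h for recombination and synapsis. The 2 h side of this comparison is a single library, so its SE and p-values rest on the spread at other times and on the assumption that the 2 h library varies like the others. Between the 2 h library and the 4 libraries from 2.25 to 3 h, a comparison added after the data were seen, MEI5, a partner of the strand-exchange protein, went from 0.610 FPKM to a mean of 650 FPKM (n = 4), a log2 change of 8.53 ± 0.88 (SE, limma adjusted p = 1.13e-05). HOP1, a chromosome axis protein, went from 1.23 to 258 ± 97.3 FPKM (SD, n = 4, log2 change 6.76, limma adjusted p = 1.57e-05), REC8, the meiotic cohesin, from 2.01 to 288 ± 147 FPKM (6.36) and IME2 from 3.44 to 351 ± 93.8 FPKM (6.26). MEK1, a checkpoint kinase, rose by a log2 change of 7.12, NDJ1, which tethers telomeres, by 6.70, ECM11 by 6.14, SAE3 by 6.06 and SPO13 by 5.96. HED1 rose by 6.03, with 49.1% of it overlapping another row. Of the 32 recombination and synapsis genes, 22 rose over all genes tested and 31 when adjusted over the list alone, with a median log2 change of 4.74. The list passed limma's camera test (adjusted p = 1.14e-69), and also with an estimated correlation (adjusted p = 0.0169).

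In the same comparison 4 of the 16 meiotic regulators rose (7 adjusted over the list alone). They were IME2, PHO92 (log2 change 5.71), a reader of RNA methylation, SLZ1 (5.02) and IME4 (4.40). IME1 itself, at 818 FPKM at 2 h, had a log2 change of 2.62 and missed the test (limma adjusted p = 0.209). CUP1-1 (4.71) and CUP1-2 (3.92) rose among the 4 copper-activated genes. The DNA replication list had a median log2 change of 1.47 with 0 of 46 members called (0 adjusted over the list alone; 532 of all genes had an unadjusted limma p under 0.05). Its camera adjusted p was 4.24e-13, and its adjusted p was 0.214 with an estimated correlation. The median of the DNA replication list was 8.99 FPKM at 2 h, 8.74 FPKM at 2.25 h and 38.3 FPKM at 3 h. Above that median at 3 h, RNR1, of deoxynucleotide synthesis, was at 12.7 FPKM at 2 h and 108 FPKM at 3 h, and POL1, a DNA polymerase subunit, at 4.32 and 91.1 FPKM. Lower after 2 h were GLN1, glutamine synthetase (193 to 9.93 ± 6.68 FPKM), ISF1, the siderophore transporter SIT1, the mannoprotein FIT2, ICL1, of the glyoxylate cycle (298 to 39.6 ± 34.8 FPKM), NRG2, DAL5 and ASN1, with log2 changes between -4.31 for GLN1 and -2.63 for FIT2. The 0 h library was high too for GLN1 (164 FPKM), ISF1 (200 FPKM), SIT1 (120 FPKM), ICL1 (323 FPKM) and FIT2 (208 FPKM). It was not for NRG2 (29.7 FPKM), ASN1 (10.8 FPKM) or DAL5 (0.425 FPKM), whose lower values rest on the 2 h library alone. SIT1 and FIT2 were the 2 of 22 copper and iron uptake genes called lower (6 adjusted over the list alone), and CTR1 was at 2.45 FPKM at 2.25 h.

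In all limma called 63 genes, 54 higher and 9 lower than at 2 h, against 68 higher and 19 lower after scaling, which shared 53 and 8 of them. No fit can leave out the 2 h library, so these counts carry no check of it. Without the 2.25 h library the count was 130. The calls of ISF1, DAL5, ASN1, NRG2, ICL1, FIT2 and CUP1-2 were lost without the 2.75 h library, all but those of ICL1 and FIT2 also without 2.5 h, and those of ISF1, DAL5 and ASN1 also without 3 h. ISF1 was lost as well without 3.25, 3.5, 3.75, 4.25, 4.5, 5, 5.25 or 5.5 h. The largest values in such fits were limma adjusted p = 0.114 for ISF1, 0.0866 for DAL5, 0.0867 for ASN1, 0.0567 for NRG2 and ICL1, 0.0578 for FIT2 and 0.0800 for CUP1-2. DAL5 missed the threshold after scaling with a change as large (log2 change -3.48, limma adjusted p = 0.0640).

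**Figure D3:**
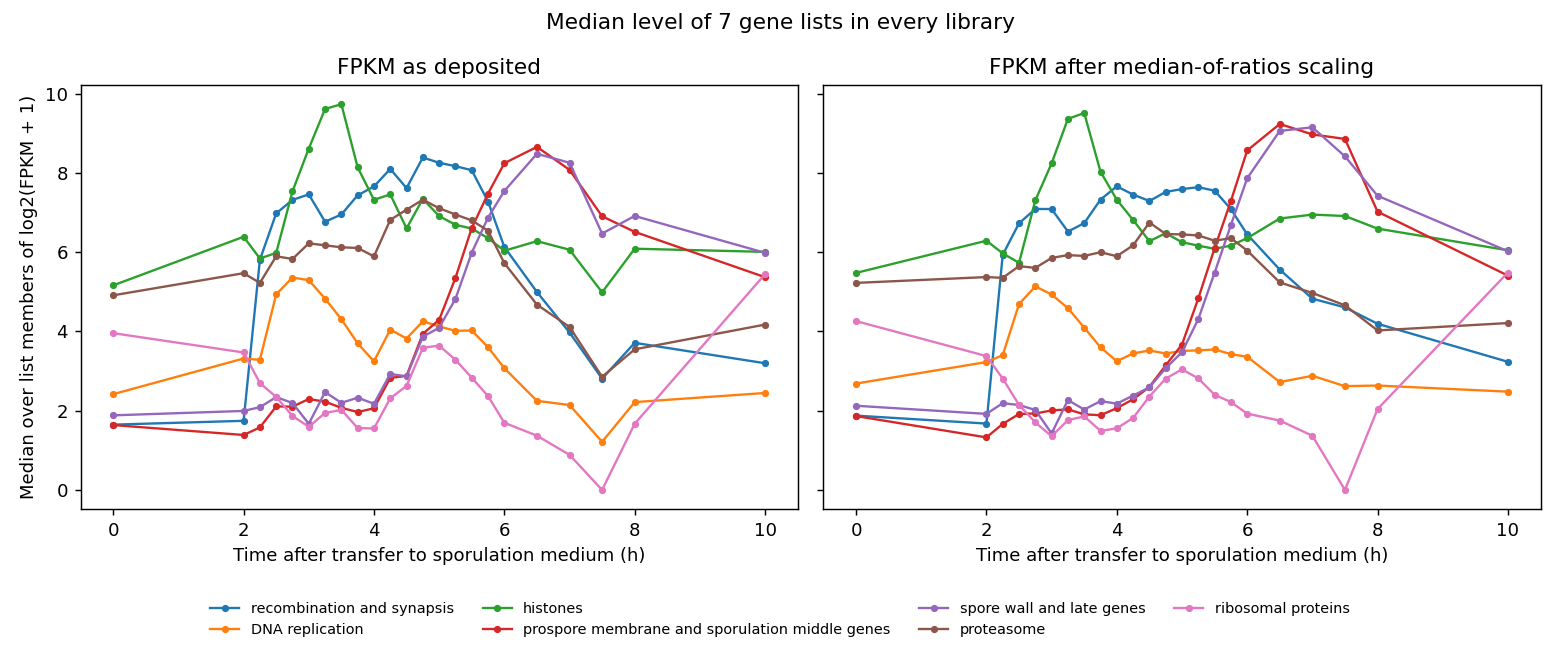
Median of log2(FPKM + 1) over the members of 7 gene lists in each of the 23 libraries against hours after transfer, with deposited values on the left and values after median-of-ratios scaling on the right; each point is 1 library. The recombination list went from a median of 2.36 FPKM at 2 h to 335 FPKM at 4.75 h, the histone list peaked at 851 FPKM at 3.5 h, and the list of prospore membrane and sporulation middle genes reached 403 FPKM at 6.5 h (deposited values).

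From the first to the second window, 3.25 to 4.5 h against 2 to 3 h, 3 glycolytic genes fell. TDH3 went from 138 ± 92.6 FPKM (SD, n = 5) to 9.50 ± 3.01 FPKM (n = 6), a log2 change of -3.35 ± 0.58 (SE, limma adjusted p = 0.0174), ENO1, enolase, from 23.4 to 2.12 FPKM (-2.64, limma adjusted p = 0.0235) and PGI1 from 20.6 to 1.92 FPKM (-2.44, limma adjusted p = 0.0449). These were the 3 of 25 glycolysis genes that fell (9 adjusted over the list alone). The list passed camera (adjusted p = 3.59e-12) but not with an estimated correlation (adjusted p = 0.477). FLO11, a cell surface flocculin, went from 3653 ± 2264 to 624 ± 169 FPKM (-2.30), PIR3, a cell wall protein, from 71.5 to 11.1 FPKM (-2.29), YRO2 from 15.4 to 1.79 FPKM (-2.34), ARG3, of arginine synthesis, from 69.0 to 18.5 FPKM (-1.86), ZTA1 from 99.0 to 28.5 FPKM (-1.72) and SSH4 from 32.8 to 13.4 FPKM (-1.27).

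The named rises between these windows were NHP6A, a chromatin protein with 66.3% of it overlapping another row (40.4 to 148 FPKM, log2 change 1.86), ARO10 (13.3 to 41.5 FPKM, 1.62) and CRP1 (56.8 to 175 FPKM, 1.62). Histones had a median log2 change of 1.42 with 0 of 10 called (4 adjusted over the list alone; 777 of all genes had an unadjusted limma p under 0.05), a camera adjusted p of 1.53e-06 and an adjusted p of 0.477 with an estimated correlation. Recombination genes had a median change of 1.41 with 0 of 32 called (1 adjusted over the list alone; camera adjusted p = 1.08e-11, and adjusted p = 0.749 with an estimated correlation). The first window holds the 2 h library, where the recombination list had a median of 2.36 FPKM. From that library to 2.25 to 3 h its median log2 change was 4.74. Part of the change of 1.41 is therefore the rise already described after 2 h. IME1, at 5053 ± 3869 and 2166 ± 701 FPKM, did not pass (log2 change -0.77, limma adjusted p = 0.632).

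In all 15 genes changed between the first windows, 5 higher and 10 lower, and 64 after scaling, 30 higher and 34 lower. The trend within each window adds to the error here, and single libraries decide the count. Without the 2.25 or the 2.5 h library limma called 0 genes, with 581 and 630 at an unadjusted p under 0.05, so every call named for these windows was lost in at least 1 such fit. The count was 5 without the 3.5 h library, 4 without 3.75 h, 5 without 4 h, 7 without 4.5 h, and 9 without the 4.75, 5, 5.25, 5.5 or 5.75 h library. It was 48 without the 3 h library, 30 without 6.5 h, 34 without 7.5 h and 41 without 10 h.

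From the second to the third window, 4.75 to 6 h against 3.25 to 4.5 h, NDT80 and 28 of 32 genes of the middle programme rose (17 of 32 after scaling). NDT80 went from 9.89 ± 9.77 to 183 ± 126 FPKM (SD, n = 6 and 6), a log2 change of 4.22 ± 0.60 (SE, limma adjusted p = 0.000384). RRT5 rose by 6.39 (5.38 to 1370 FPKM), SPS4 by 5.85 (10.9 to 1680 FPKM), SPS2, a spore wall protein, by 5.56, and SPR3, a sporulation septin, by 5.49 (4.96 to 504 FPKM). PES4 rose by 5.39, SPO74, of the meiotic spindle pole body, by 5.25, SSP1, of the leading edge of the prospore membrane, by 4.77, IRC18 by 5.46 and SPR2 by 5.24. Of the 32 prospore membrane and sporulation middle genes, 28 rose (29 adjusted over the list alone) and 17 did after scaling. This list passed camera (adjusted p = 7.6e-33), with adjusted p = 0.0803 with an estimated correlation. Of the 28 spore wall and late genes, 18 rose over all genes and adjusted over the list alone, and 12 after scaling, among them LDS1 (5.53) and LDS2 (4.55), of lipid droplets in spores, and CDA2 (4.97), a chitin deacetylase of the spore wall. It passed camera (adjusted p = 3.04e-20), also with an estimated correlation (adjusted p = 0.0482).

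Of the 35 genes of the meiotic divisions, 7 rose between these windows (11 adjusted over the list alone, 4 after scaling), among them the polo kinase CDC5 (9.16 to 252 FPKM, log2 change 3.76), MAM1 of the monopolin complex (3.73) and the anaphase activator CDC20 (3.01). Their camera adjusted p was 0.000563, and the adjusted p was 0.901 with an estimated correlation. SSA3, a heat shock protein, rose from 129 ± 49.7 to 611 ± 144 FPKM (2.29) and PCK1, of gluconeogenesis, from 21.4 to 112 FPKM (2.57). Of the 25 haploid-specific and mating genes, markers of another cell type, FUS2 (3.72 to 20.3 FPKM), PRM1 (1.07 to 4.17 FPKM) and STE5 (2.77 to 8.22 FPKM) rose (7 adjusted over the list alone), with STE5 past the threshold only as deposited (log2 change 1.27, and 1.13 after scaling with limma adjusted p = 0.170). Of the 10 histones HTB2 (390 to 40.5 FPKM, -3.02) and HHT1 (869 to 127 FPKM, -2.20) fell (5 adjusted over the list alone), and the list's camera adjusted p of 1.42e-08 became an adjusted p of 0.152 with an estimated correlation. SIM1, of the SUN family, fell from 35.4 to 11.9 FPKM (-1.68) and the permease MEP2 from 42.9 to 7.82 FPKM (-2.45). The RNA genes SNR8, RDN5-1 and RDN5-2 had changes of -2.17, -1.82 and -2.08. The RDN5 rows are copies of a gene, and 88.2% of RDN5-2 overlaps another row.

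In all 222 genes changed between these windows, 211 higher and 11 lower, and 102 after scaling, 73 higher and 29 lower; the median of all genes moved by 0.14, and 73 rises and 10 falls were called both ways. The count was 143 without the 3.25 h library, 121 without 3.5 h, 147 without 3.75 h, 142 without 4 h, 117 without 5.5 h, 98 without 5.75 h and 118 without 6 h. HTB2, HHT1, MEP2, SNR8 and STE5 each lost their calls without the 3.25, 3.5, 3.75, 5.5, 5.75 or 6 h library, and RDN5-2 without 5.5 or 5.75 h. Further losses were without 4 h for HTB2, SNR8 and STE5, 4.25 h for SNR8, 4.5 h for MEP2, SNR8 and STE5, 5.25 h for HHT1 and MEP2, and 2, 2.25, 2.5, 2.75, 3 or 8 h for STE5. The largest values were limma adjusted p = 0.113 for HTB2, 0.1065 for HHT1, 0.118 for MEP2, 0.116 for SNR8, 0.0621 for RDN5-2 and 0.122 for STE5.

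From the third to the last window, 6.5 to 10 h against 4.75 to 6 h, the median gene fell by 0.99 on the log2 scale, so where a pair of log2 changes follows a gene, the first is as deposited and the second after scaling, where the median change was -0.06. FPKM values are as deposited. GAT4, a putative GATA factor, rose from 19.7 ± 29.8 FPKM (SD, n = 6) to 1286 ± 535 FPKM (n = 5), by 7.18 ± 0.77 (SE, limma adjusted p = 1.01e-06) and 8.18. SGA1, a sporulation glucoamylase, rose by 5.36 and 6.51 (42.9 to 994 FPKM), CTS2, a putative chitinase, by 5.18 and 6.32, and HXT10, a hexose transporter, by 4.77 and 5.92. SPR6 rose by 4.55 and 5.72, and UBC11, a ubiquitin-conjugating enzyme, by 4.49 and 5.67. SOL1 rose by 4.36 and 5.53, the kinase SPS1, of spore wall assembly, by 4.34 and 5.50, SPS4 by 4.30 and 5.50 (1680 to 13686 FPKM) and GLN1 by 3.92 and 5.11. Of the 32 prospore membrane and middle genes 14 rose (14 adjusted over the list alone, 22 after scaling), among them SSP2 (4.04 and 5.23) and SPS22 (3.64 and 4.81). Of the 28 spore wall genes 13 rose and 2 fell (14 and 2 adjusted over the list alone, 19 and 0 after scaling), with SPR1, a glucanase, up by 3.78 and 4.96 and RRT12 by 3.64 and 4.78. Camera adjusted p-values for these lists were 4.55e-15 and 3.3e-11, with adjusted p = 0.600 and 0.390 with an estimated correlation.

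All 32 recombination genes fell in the last window (32 adjusted over the list alone, 27 after scaling). DMC1, the meiotic recombinase, fell from 546 ± 201 to 23.8 ± 19.7 FPKM, by 4.62 and 3.45 on the log2 scale (limma adjusted p = 5.21e-05 as deposited), PCH2 from 217 to 9.70 FPKM and REC114, of break formation, fell by 4.40 and fell by 3.26 after scaling. The camera adjusted p of the list was 1.77e-07, with adjusted p = 0.792 with an estimated correlation. All 33 proteasome genes fell (33 adjusted over the list alone, 29 after scaling), among them PRE9 (56.2 to 3.38 FPKM), PRE1 (193 to 15.6 FPKM) and RPN3 (121 to 9.39 FPKM), with a camera adjusted p of 1.14e-14 and adjusted p = 0.600 with an estimated correlation. Of 44 genes of the TCA cycle and respiration 35 fell (35 adjusted over the list alone, 19 falls and 2 rises after scaling), with IDH1 from 134 to 5.13 FPKM and FUM1 from 300 to 24.1 FPKM (camera adjusted p = 2.51e-05, and adjusted p = 0.792 with an estimated correlation). Of 24 glyoxylate and gluconeogenesis genes 17 fell and 1 rose (18 and 1 adjusted over the list alone, 12 and 2 after scaling), with CIT3 from 847 to 43.5 FPKM and MLS1 from 470 to 28.9 FPKM (camera adjusted p = 0.0109, and adjusted p = 0.792 with an estimated correlation). IME1 fell from 2237 ± 668 to 216 ± 118 FPKM, by 3.48 and 2.27, and RIM4, an RNA-binding repressor of middle gene translation, from 1503 to 97.1 FPKM. IME4 fell by 2.75 as deposited, while its scaled change of -1.55 missed the test (limma adjusted p = 0.0599). PDH1 (425 to 16.8 FPKM), the agglutinin subunit AGA2 (160 to 6.95 FPKM), HED1, DPI8 and RNP1 also fell. As deposited, JIP3 fell by 5.17 and TIR1 fell by 4.50. JIP3 lies under MID2 over 98.2% of its length and RNP1 under another row over 45.6%.

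Other lists were mixed in the last window. Of 35 division genes 6 rose and 11 fell (5 and 11 adjusted over the list alone, 14 and 4 after scaling); CDC27, of the anaphase-promoting complex, rose by 2.90 and 4.09 and MND2, of the same complex, fell by 3.38 and 2.31. The median of this list was 0.18, its mean -0.25 and its camera direction up against other genes (adjusted p = 0.00634, adjusted p = 0.0769 after scaling, and adjusted p = 0.792 with an estimated correlation). Of 46 DNA replication genes 28 fell and 2 rose (30 and 2 adjusted over the list alone, 14 and 2 after scaling), with RFA1 from 68.7 to 4.70 FPKM, and of 36 stress genes 18 fell and 1 rose (19 and 1 adjusted over the list alone, 10 and 2 after scaling), with HSP42 from 401 to 46.4 FPKM. Neither passed camera as deposited (adjusted p = 0.0701 and 0.139), and the replication list did so only after scaling (adjusted p = 0.0189), with adjusted p = 0.792 with an estimated correlation on the deposited values. Ribosomal protein genes, of which 15 of 132 fell (0 adjusted over the list alone), had a median of -0.90 and lay above other genes in camera (adjusted p = 0.0288). After scaling 5 rose and 2 fell, with camera pointing down (adjusted p = 0.839); the estimated correlation gave adjusted p = 0.792. The upward direction rested on the 10 h library, without which the median was -1.76 and camera pointed down (adjusted p = 0.205, and 0.00145 after scaling), a fit added after the data were seen. Ribosome biogenesis genes had 4 rises and 11 falls of 80 (1 and 6 adjusted over the list alone; 16 and 5 after scaling), a median of -0.42 and a camera direction up (adjusted p = 0.000847, adjusted p = 0.792 with an estimated correlation, and adjusted p = 0.497 without the 10 h library). Of 25 mating genes 3 rose and 9 fell (3 and 9 adjusted over the list alone), while after scaling 6 rose and 3 fell. Of 26 mitotic G1 and budding genes 13 fell (13 adjusted over the list alone, 4 falls and 2 rises after scaling).

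In all 3144 genes changed into the last window, 268 higher and 2876 lower, and 2154 after scaling, 1034 higher and 1120 lower. All 268 rises and 1120 of the falls were called both ways. The windows differ in level as well as in time, the 7.5 h library having the lowest level of all.

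The order of the programme was asked with the time of each rising gene's fitted maximum. The 30 recombination genes called as rises peaked at a median of 4.35 h (mean 4.33 ± 0.22, SD), the 32 middle genes at 7.22 h (7.21 ± 0.77) and the 25 spore wall genes at 7.30 h (7.73 ± 1.29). The spore wall genes DIT1, DIT2, RRT8, SPS100 and SHC1 and the middle gene AQY1 had their fitted maximum at 10 h, the last time sampled. These are edge values of curves still rising, and they raise the spore wall mean most. The comparisons of means below were not repeated without them. The mean of the middle list lay 2.88 h after that of the recombination list, and that of the spore wall list 3.41 h after it (both permutation p = 2e-05, the smallest the resamples can give, and adjusted p = 3e-05, two-sided permutation tests). The spore wall list lay 0.53 h after the middle list, a difference that missed the threshold (permutation p = 0.0626, adjusted p = 0.063 over the 3 pairs). With a spline of 6 degrees of freedom it was 0.81 h (permutation test, adjusted p = 0.023). By the highest library it was 0.52 h (permutation test, adjusted p = 0.091), and over all tested members 0.003 h (permutation p = 0.996). The order of the middle and spore wall lists therefore stays open. Peak times and their spread depend on the curve. With 6 degrees of freedom the medians were 4.8, 6.6 and 7.15 h for the recombination, middle and spore wall lists. The SD of the recombination genes was then 0.80 h. By the highest library the medians were 4.75, 6.5 and 7 h, with recombination genes from 2.5 to 5.5 h (SD 0.75 h). Genes of a list are not independent replicates, so the permutation tests describe the lists in this course.

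**Figure D4:**
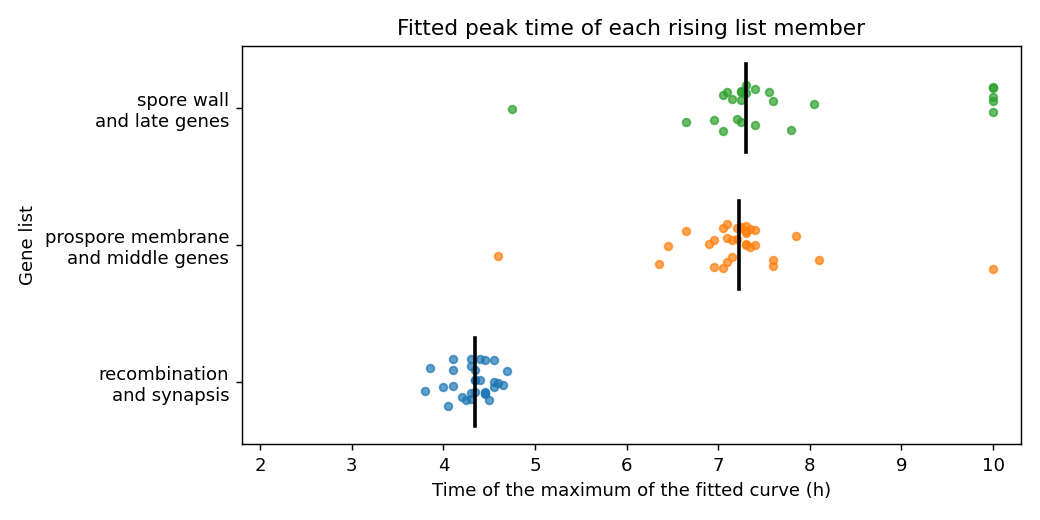
Time of the maximum of the fitted curve (hours) for each member called as a rise in 3 gene lists; points are genes, spread vertically for clarity, and black bars are list medians. The medians are 4.35 h for 30 recombination genes, 7.22 h for 32 middle genes and 7.30 h for 25 spore wall genes. Points at 10 h lie at the end of the sampled times and are edge values.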

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

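All results rest on 1 library per time, and depth limits genes near 1 FPKM, most of all in the 7.5 h library. The time test gave 5447 genes and between 4598 and 5572 under its other alternatives. Those of a mean of at least 10 FPKM (3613) and of genes overlapping no other row (4548) are set apart, since they test fewer genes. Leaving out each library in turn gave 5209 to 5494. For 3.25 to 4.5 h against 2 to 3 h, the 15 genes became 25 with a pseudocount of 5 FPKM, 64 with median-of-ratios scaling, 134 with quantile normalisation, 6 and 51 with window borders 1 library later and earlier, 630 with spline-fitted values, and 0 to 48 with each library left out. For 4.75 to 6 h against 3.25 to 4.5 h, the 222 genes became 102 with scaling, 363 and 80 with borders later and earlier, 775 with spline-fitted values, and 98 to 314 with each library left out. For 6.5 to 10 h against 4.75 to 6 h, the 3144 genes became 2080 with a pseudocount of 5 FPKM, 1988 with quantile normalisation, and 2522 to 3760 with each library left out. The added contrast of 2.25 to 3 h with 2 h gave 63 genes, 128 with quantile normalisation, and 46 to 130 with each library left out. The cause was not tested. Without the 4.5 and 7.5 h libraries together, an alternative chosen after seeing the data like those on overlapping and short rows, the counts were 5296 for the time test, 16, 228 and 2501 for the windows and 62 for the added contrast.

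The lists that passed camera numbered 13, 14, 9 and 9 of 21 in the 4 contrasts in order of time. With an estimated correlation 1, 0, 1 and 0 passed (6, 2, 3 and 1 at an unadjusted p under 0.05), and with fry 5, 0, 2 and 15 (7, 2, 5 and 15 unadjusted). Fry after scaling, added after seeing the data, gave 8, 0, 3 and 9, and the nitrogen starvation list of the last contrast passed fry downward as deposited and upward after scaling (adjusted p = 0.0487 and 0.0357). Fry tests against no change, and the median gene fell by 0.99 as deposited. The ribosomal protein list in the last contrast pointed up as deposited and down after scaling (adjusted p = 0.83868), and down without the 10 h library (adjusted p = 0.20505), an added fit in which 9 lists passed. The cause was not tested for the scaling. The difference of 0.53 h between the spore wall and middle lists passed with 6 degrees of freedom (0.808839 h) and was 0.52 h with the highest library and 0.003 h over all tested members. The count of 1367 genes between 0 and 2 h lay between 1013 and 1581 under its alternatives. Among named genes, 411 of the refitted values lost their call, 2 gained it, 5730 stayed on their side of the threshold and none turned direction while called. A count test was not run, since whole reads could not be recovered.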

Other observations

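The tests of orders and splits of the libraries, the share on listed genes, the 7.5 h library, the scale of the 4.5 h and 10 h libraries, the copper genes and the budding genes were chosen after the results were seen. In 1 of 100 orders of the times, the real one, the time test called as many as 5447 genes; the highest other order gave 202. For the windows in order, 1 of 100 splits each, the real one, gave as many genes as the 15, 222 and 3144 called, the highest other splits giving 9, 54 and 2195. Chance can be excluded in the sense that the libraries are not exchangeable over time. In a smooth course windows of consecutive times exceed splits that break the order, so these splits do not test the place of the borders, and the 15 genes, which became 0 without the 2.25 or the 2.5 h library, are left open.

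Between 8 and 10 h, single libraries with no test, several lists stood higher and others lower. After scaling, the median log2 difference was 3.11 for 132 ribosomal protein genes (131 higher), 1.16 for 80 ribosome biogenesis genes (73 higher), 0.99 for 33 translation factors (30 higher) and 1.23 for 25 glycolysis genes (18 higher). The first 3 lay above all 10000 random lists matched on level. Random lists hold unrelated genes, while genes of a list tend to move together, so this rank adds little to the medians. RPL3 was at 8.41 FPKM at 8 h and 68.1 FPKM at 10 h, and NSR1, a nucleolar protein, at 0.667 FPKM at 7.5 h, 20.2 FPKM at 8 h and 38.3 FPKM at 10 h, with 46.9% of it overlapping another row. Other lists were high too, at 0.91 for glyoxylate cycle and gluconeogenesis (18 of 24 higher), 0.74 for amino acid biosynthesis (35 of 45) and 0.37 for heat shock and general stress (23 of 36). The TCA cycle and respiration list was split, with 22 of 44 higher and a median of 0.03 (95% bootstrap bounds -0.38 to 0.46). Bootstrap bounds resample the genes of a list as if independent and hold no spread between libraries. Lists of the meiotic programme stood lower, by -1.95 for middle genes, -1.81 for spore wall, -1.34 for divisions, -0.98 for regulators and -0.95 for recombination.

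The rise of ribosomal protein genes at 10 h is not a matter of the scale of that library, since their median remained 3.11 after scaling (95% bootstrap bounds over genes 2.83 to 3.50). These bounds do not measure how far another 8 or 10 h library would differ. Dividing cells in the 10 h library may contribute. The mitotic G1 and budding list had a scaled median of -0.345 (8 of 26 higher). It stood at 2.82 FPKM at 8 h against 2.19 FPKM for ribosomal protein genes, so its own baseline could hide a small share. The DNA replication and histone lists did not rise either, with scaled medians of -0.227 (17 of 46 higher) and -0.463 (4 of 10 higher). All of these rest on 1 library at each time, so the question stays open. The time itself, a late stage of the course, is the biological difference in the design and was not tested apart from the single library.

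The lower level of the median gene over 6.5 to 10 h, -0.99 on the log2 scale, could come from several sources. The low stretch did not match the window. The median stood at 7.85 FPKM at 6 h, in the window before, and at 6.52 FPKM at 8 h. At 10 h it was back at 11.4 FPKM, near the 11.1 FPKM of the 5.75 h library. Without the 10 h library the change was -1.22. The share of mapped fragments on listed genes changed by a mean of -0.339 (log2, SE 0.186), too little for the whole change relative to the total behind the deposited FPKM. What that total counts is not known, so the share is not a measure of messenger RNA. Without the 7.5 h library the median change was still -0.760, which argues against that library alone. The share left to genes outside the 50 highest of a library changed by -0.259 (SE 0.06), short of the -0.3 set beforehand but beyond -0.1, so a few genes taking more fragments may account for a part and cannot be told apart from other sources. A decline in RNA per cell late in meiosis stays open as untested, since RNA per cell was not measured.

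IME1, IME4, CUP1-1 and CUP1-2 were low in the 4.5 h library, CUP1-1 at 365 FPKM against 945 FPKM at 4.25 h and 1501 FPKM at 4.75 h. After scaling, their deviation from the neighbouring libraries was -0.72, -0.25, -1.27 and -1.73, with a mean of -0.994 (SE 0.323). The deviations lay at percentiles 7.7, 29.7, 3.2 and 2.3 of genes with a mean of at least 10 FPKM, so that of IME4 was unremarkable. CUP1-1 and CUP1-2 are near-identical copies, while the SE takes the 4 genes as independent. The scale of the library (log2 0.327, against 0.650 at 4.25 h and 0.873 at 4.75 h) may account for part of the low deposited values. The deviations given remain after scaling. The 4.5 h library ranked 3 of 20 in the deviation of all genes from its neighbours. That lay between the ranks set beforehand for a misplaced library and for a well placed one. The libraries ranked 1, 2, 4 and 5, at 7.5, 8, 7 and 6.5 h, have neighbours further away in time, so the rank cannot settle this. Among libraries with neighbours as close as its own, the 4.5 h library deviated most (0.333), ahead of the 2.25 h library (0.256). CRS5 and SOD1, other copper-activated genes, deviated by -0.81 and 0.92, and their mean stood at percentile 55.0 of random pairs. None of these explanations was excluded, and a passing change in copper was not measured.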
